A study of Mus musculus with 4 samples.

How the data were processed

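RNA sequencing of mouse Th17 cells was analysed in 4 libraries, which the labels number as biological replicates 1 to 4 of 1 group. The authors' deposited files held whole-number counts of read pairs per gene, not normalised. Per the file headers, the counts were made with featureCounts 1.4.6-p4 on exons of GENCODE mouse release 13, summed by gene, with read pairs counted once, both mates required to align, and the reverse-stranded setting (option 2). Per the file headers, reads that map to several places and reads that overlap several genes were not counted, which sets genes with a near-identical copy, and genes under a neighbour on the same strand, too low. The input name in the headers points to STAR as the aligner, its version is not given in the sources used here, and the genome build is mm10 per the labels. The library names in the headers include the word sorted, and all 4 carry 1 run name, so no sequencing batch could be told from them. The labels call the assay total RNA sequencing, while the library protocol they link is named for RNA with poly(A) tails.

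The 4 files listed the same 50600 genes, of which 21299 had a count in some library. Gene symbols and types were taken from GENCODE mouse release 21, where 50376 of the identifiers were found after dropping version numbers; the other 224 held 0.0104% of the counts. Coordinates are those of the files, in mm10. Totals ran from 9382661 to 34542693 counts. A count of 0 allows up to 3 counts in a library, and intervals and floors cover counting error only (95%, exact Poisson).

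The analysis plan was written for estimated counts and TPM from the authors. Since the deposited values are counts, TPM were computed here from the counts and the exonic lengths in the files, with no correction for fragment length, and an alternative meant for posterior mean TPM was not run. No rounding was needed. Very short genes get inflated TPM in this way. The libraries of each pair differed by more than sampling noise (chi-square per gene from 3.32 to 18.55 over genes with at least 20 counts), as repeat preparations of 1 sample would too. All 4 were kept as separate replicates because the labels number them so. Sex-linked genes, given in the results, argue against 1 animal behind all 4.

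For the contrasts, log2(TPM + 1) was averaged over list members in each library, and differences between lists or genes were tested over the 4 libraries with an exact sign-flip permutation test (both tails) and Benjamini-Hochberg adjustment within each family (5 list contrasts, 12 gene pairs). List levels were set against 10000 random lists of protein-coding genes of the same size. For the spread between libraries, edgeR 4.0.16 was fitted with an intercept alone (TMM normalisation, filterByExpr), and each gene's quasi-dispersion was divided by its abundance trend and tested against the F distribution (upper tail, adjusted p of 0.05). The estimated prior degrees of freedom were 4.78 and the common biological coefficient of variation 9.13%. The 7 splits of the libraries (4 of 1 against 3, and 3 of 2 against 2) were fitted with edgeR's quasi-likelihood test. List variability was the median coefficient of variation of TMM-normalised CPM over the list's genes that passed the filter, set against 10000 random lists matched in 10 bins of expression. The shift of a list in a library used log2(CPM + 1) in the same way. Percentiles describe these libraries and are not tests.

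The methods were tested on simulated data, with counts drawn from the real means, library sizes and trended dispersion and 200 genes changed. With no gene changed, the variable-gene test and the splits called 0 of 11985 genes. For genes changed in 1 of 4 libraries, the variable-gene test recovered 60% of 2-fold and 90% of 4-fold changes among 11997 genes. For the split of 1 against 3, edgeR recovered 80% and 98% among 12002 genes, with 8 false calls of 186. For the split of 2 against 2, it recovered 87% and 100% among 12000 genes, with 12 false calls of 199. The simulated genes all followed the trend, and no simulation with spread around the trend was run, so these rates do not carry over to the data. There, 25 genes with 2.08-fold to 6.92-fold between the extreme libraries stayed above the threshold. Their adjusted p ran from 0.2891 to 0.4245 in the variable-gene test. The split of replicates 1 and 2 against 3 and 4 did not call Xist.

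The 30 gene lists, the 12 gene pairs, the tests and the alternatives were fixed before the data were examined. The text names members of the gene pairs, any member of the Th17, Th1, Th2, Treg and Tfh lists, the 5 highest members and the members below 1 TPM of the other lists, the 20 most abundant protein-coding genes outside mitochondrial and ribosomal protein genes, the 25 variable genes with the smallest adjusted p, list members past that threshold, and the sex-linked list. Other genes were chosen after their values were seen, among them members of the 2 Th17 signatures outside their 5 highest, the list members called in the split of replicate 4, Usp18, the genes ranked after Xist, and the mitochondrial, histone, pseudogene and hypoxia target genes. Results for 3 genes, among them 4 of the 12 gene pairs, are not reported here. The values screened for a library far from the others were also chosen after values were seen. The alternatives were other detection limits (0.5 and 5 TPM, 10 counts), a pseudocount of 0.1 TPM, CPM, the median over list members, members above a minimum, other normalisation (DESeq2 size factors), no filter, a mean of at least 50 counts, a robust prior, limma-trend, DESeq2 1.42.0, an adjusted p of 0.01, and leaving out each replicate. For the splits, 3 alternatives were chosen after seeing the data, namely libraries thinned to 1 depth, removal of a smooth trend on GC content and exonic length (loess, span 0.3), and leaving out each replicate. The share of 50-base words that a gene shares with others was computed from the transcripts of GENCODE release 21. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.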

Results

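The transcriptome of mouse T-helper 17 (Th17) cells, a class of CD4 T cell defined by the secretion of interleukin 17, was measured by RNA sequencing in 4 libraries of 1 group. The labels describe primary cells of the C57BL/6NJ strain, numbered as biological replicates 1 to 4. Each library has its own biosample, and all 4 share 1 donor label. Sex was not recorded in the labels, and the library names in the file headers carry the mark 72 hr. The files held counts of read pairs for 50600 genes. Total counts were 34542693 in replicate 1, 23673174 in replicate 2, 9382661 in replicate 3 and 28629187 in replicate 4, a 3.68-fold range. A count of at least 1 was seen for 18778, 18019, 16009 and 18571 genes in replicates 1 to 4. In every library, 11622 genes had at least 1 TPM (transcript abundance scaled to a fixed total per library), 10367 of them protein-coding. Pearson correlations of log2(TPM + 1) across all genes, those without a count in any library included, lay between 0.992 and 0.996 for the 6 pairs of libraries (genes are not independent replicates). Over the 12573 genes with at least 1 TPM in the mean they lay between 0.975 and 0.990. With no second group, the comparisons are between genes and gene lists within the same library, and between the 4 libraries. The labels do not say whether the libraries came from separate animals or cultures, so p-values measure only the spread between these samples. The sex-linked genes below argue against 1 animal behind all 4 libraries, and do not show how many there were.

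The first comparison asked how the genes of the Th17 programme stood against those of other T-cell lineages in the same cells. All 18 members of the Th17 list had at least 1 TPM in every library, and Il17f had the highest TPM in these counts of reads that map once, at 11651 ± 878 TPM (SD, n = 4). Genes with near-identical copies, some mitochondrial genes among them, are set too low in such counts, so their ranks are uncertain. Il17a, which encodes the cytokine that names the lineage, ranked 6th in the same counts at 7787 ± 754 TPM. Together both cytokine transcripts took between 0.895% and 1.06% of all counts. In mm10 coordinates, Il17f (ENSMUSG00000041872.9) lies on chromosome 1 from 20777146 to 20790617, and Il17a (ENSMUSG00000025929.4) from 20730905 to 20734496. The transcription factor gene Rora stood at 40.2 ± 4.93 TPM (SD, n = 4). The chemokine gene Ccl20 had 973 ± 151 TPM and its receptor gene Ccr6 174 ± 11.5 TPM. Among other transcription factor genes, Irf4, Batf, Stat3, Maf and Ahr had 698 ± 10.8, 389 ± 24.0, 210 ± 13.5, 119 ± 4.13 and 46.0 ± 11.8 TPM. Il21, a cytokine shared with T follicular helper cells, reached 597 ± 21.5 TPM, while Il22 was the lowest member of the list at 25.01 ± 8.95 TPM. The receptor genes Il12rb1, Il23r and Il1r1 had 230 ± 13.02, 80.2 ± 5.95 and 59.1 ± 9.73 TPM. The membrane protein genes Tmem176b and Tmem176a had 267 ± 36.5 and 166 ± 25 TPM.

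Cytokines of the Th1 and Th2 lineages were low or near the floor of detection. Ifng, the signature cytokine of Th1 cells, held 2 counts over all 4 libraries, Il4 held 18 and Il5 held 1, and Il13 had 1.46 ± 0.586 TPM (SD, n = 4). The Th1 regulator Tbx21 was measured at 20.3 ± 3.38 TPM, with Runx3 at 104 ± 11.6, Il12rb2 at 46.9 ± 18.6, Stat4 at 33.4 ± 10.4 and Cxcr3 at 25.8 ± 2.58 TPM. Of the 12 Th1 members, 10 had at least 1 TPM in every library, the exceptions being Ifng and Eomes. Of the 10 Th2 members, 6 passed that level. The regulator Gata3 had 3.19 ± 1.02 TPM, whereas the receptor genes Il4ra and Ccr4 and the signalling gene Stat6 had 262 ± 5.63, 164 ± 8.81 and 190 ± 8.88 TPM, and Ccr8 62.0 ± 13.3 TPM. The regulatory T-cell (Treg) list was split in the same way. Its regulator Foxp3 was below 1 TPM in replicates 1, 2 and 4 (0.382, 0.277 and 0.200 TPM) and at 1.85 TPM in replicate 3, and Lrrc32 had 0.743 TPM. By contrast Ctla4 and Il2ra were among the most abundant transcripts of the cell, at 2801 ± 373 and 1539 ± 63.5 TPM, and Tnfrsf18, Ebi3 and Tigit had 287 ± 85.0, 123 ± 23.8 and 30.6 ± 8.74 TPM. Among follicular helper (Tfh) genes, Bcl6 had 7.42 ± 0.693 TPM and Cxcr5 11.3 ± 2.94 TPM, while Pdcd1, Btla and Icos had 452 ± 70.3, 174 ± 18.6 and 117 ± 29.6 TPM.

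**Figure D1:**
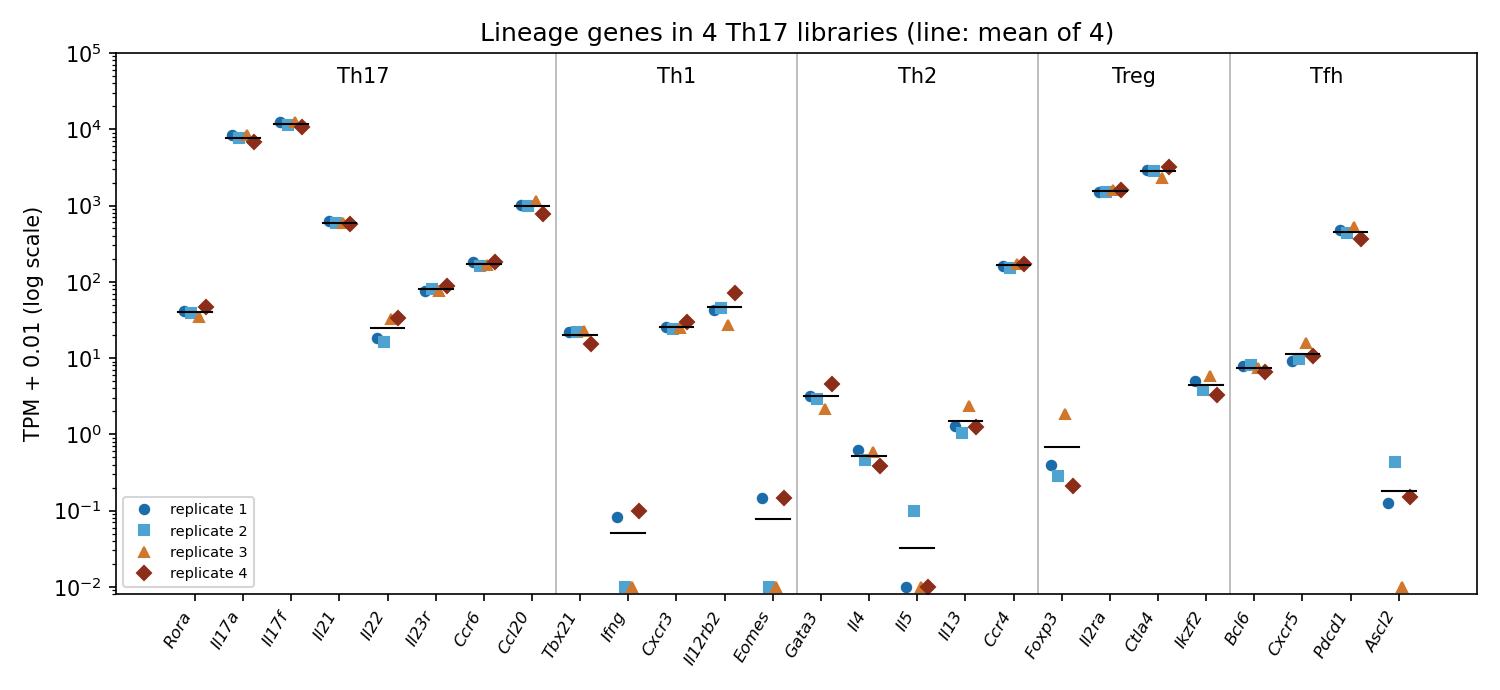
TPM plus 0.01 on a log axis for 26 genes of 5 T-helper lists in each of the 4 Th17 libraries; each symbol is 1 library, and the line is the mean of 4. Il17f and Il17a lie highest in every library, while Ifng held 2 counts and Il5 held 1 over all libraries.

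On the scale of mean log2(TPM + 1) over list members, with shared members left out, the Th17 list exceeded the Th1 list by 4.49 ± 0.157, the Th2 list by 4.70 ± 0.0574, the Treg list by 2.63 ± 0.168, the Tfh list by 3.21 ± 0.108 and the naive T-cell list by 2.57 ± 0.135 (SD, n = 4). Each difference was positive in 4 of 4 libraries. The exact sign-flip permutation test over 4 libraries (both tails) gave p = 0.13 for each of these 5 contrasts, before and after Benjamini-Hochberg adjustment. This is the smallest p that 4 libraries allow, so none could reach 0.05. The size of the contrasts depended on the summary, least for the Treg list, at 2.54 to 2.91 over the settings run. The Th1 difference ran from 3.68 to 5.08 and the Tfh difference from 2.57 to 3.56. The Th2 difference was 2.64 when only members with at least 1 TPM in some library were used, and the naive difference was 1.44 with the median over members in place of the mean.

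Of the 12 gene pairs fixed before the data were examined, 8 are given here, which set Il17a against other cytokines and Cd4 against Cd8a. Il17a exceeded Il21 by 3.70 ± 0.0998 log2 units (SD, n = 4, on the log2(TPM + 1) scale, which understates differences from low genes). It exceeded Il10 by 7.63 ± 0.324, Csf2 by 7.68 ± 0.642, Il22 by 8.29 ± 0.588, Il4 by 12.34 ± 0.0532 and Ifng by 12.87 ± 0.185. In pooled counts per base of exon, Il17a was 15441-fold above Il4, with a 95% Poisson interval of 9770 to 26053. It was 146670-fold above Ifng, with an interval of 40602 to 1211100 set by the 2 Ifng counts. These intervals cover counting error only. Il17a was the lower member in its pair with Il17f, by -0.58 ± 0.0426 log2 units in 4 of 4 libraries, or 0.667 times Il17f in pooled TPM. Cd4 exceeded Cd8a by 9.10 ± 0.0309 log2 units, with 67582 counts for Cd4 and 4 for Cd8a, while Cd8b1 was measured at 13.4 ± 1.96 TPM. Each of the 8 pairs kept 1 sign in 4 of 4 libraries and had the smallest exact sign-flip p that 4 libraries allow, 0.13, unchanged by adjustment over the 12 pairs. Without a length correction, on counts scaled only to the library total (CPM), the Il17a to Il21 difference was 1.53 and the Il17a to Il17f difference was -1.37 log2 units.

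Among the other fixed lists, those of T-cell identity, activation, division and metabolism were high. The T-cell identity list had a median of 535 ± 8.80 TPM over its 16 members, above all 10000 random lists of protein-coding genes of its size. Its 4 highest members were Cd5 at 1384 ± 32.6, Trac at 1041 ± 97.7, Lck at 886 ± 20.4 and Trbc2 at 810 ± 104 TPM, and Cd4 stood at 564 ± 30.2 TPM (SD, n = 4). The activation list (median 318 ± 40.0 TPM) was led by Il2ra, Tnfrsf4 (1136 ± 115 TPM), Tfrc (855 ± 60.7 TPM), Irf4 and Il2 (501 ± 83.8 TPM). The cell-cycle list had a median of 291 ± 17.8 TPM, with the replication genes Pcna and Mcm3 at 509 ± 23.2 and 464 ± 24.3 TPM and the mitotic genes Cdc20 and Top2a at 392 ± 39.9 and 364 ± 14.5 TPM. All 16 glycolysis members had at least 1 TPM in every library, with Ldha, Pkm and Gapdh at 3926 ± 170, 2297 ± 182 and 2198 ± 232 TPM. The glycolysis median was 364 ± 50.4 TPM, beside 273 ± 3.54 TPM for oxidative phosphorylation and the citric acid cycle and 153 ± 3.78 TPM for cholesterol synthesis. The medians of the lists for cytokine receptors and feedback, stress and immediate early genes, and aryl hydrocarbon receptor targets were 48.3 ± 5.49, 36.7 ± 11.5 and 5.06 ± 1.06 TPM, with Cyp1b1 at 85.0 ± 19.4 TPM in the last. The naive T-cell list was at 75.3 ± 10.9 TPM, where Tcf7 and Ccr7 (220 ± 2.45 and 187 ± 31.5 TPM) stood above its other members. The interferon response list was low, at 1.14 ± 0.704 TPM, with 6 of its 12 members below 1 TPM in the mean and Bst2, at 293 TPM, its highest.

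The list medians by lineage ranked Th17 (201 ± 5.32 TPM) above Tfh (36.1 ± 2.47), Treg (34.0 ± 5.46), Th1 (15.6 ± 1.90) and Th2 (2.33 ± 0.401 TPM; SD, n = 4). Against 10000 random lists of protein-coding genes of the same size, they lay at the 100th, 96.68th, 97.09th, 88.92nd and 53.87th percentile. Against random lists of genes with at least 1 TPM in the mean, the percentiles were 100, 63.14, 49.92, 8.7 and 0.

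Markers of other cell types were low or unseen. The median was 0 TPM for the neutrophil, the mast cell and basophil, and the erythroid and platelet lists. It was 0.0484 ± 0.0619 TPM for gamma-delta and innate-like T cells and 0.0215 ± 0.0240 TPM for stromal, endothelial and epithelial cells. It was 0.0496 ± 0.0117 TPM for dendritic and antigen-presenting cells, 0.0740 ± 0.0352 TPM for macrophages and monocytes and 0.112 ± 0.0823 TPM for B and plasma cells (SD, n = 4). For natural killer cells it was 1.14 ± 0.252 TPM, with Nkg7 at 8.82 ± 3.00 and Klrd1 at 3.60 ± 0.989 TPM but Ncr1 and Klrb1c at 0 counts. For the 2 CD8 genes it was 6.72 ± 0.980 TPM. A few single members were higher: Cd74 and H2-Ab1 at 38.7 ± 5.29 and 30.3 ± 21.8 TPM, beside H2-Aa at 0 counts. Igkc, Ighm and Ebf1 had 22.5 ± 10.1, 12.98 ± 3.33 and 6.87 ± 1.38 TPM, beside Ms4a1 at 0 counts. Pecam1 and Cd68 had 8.49 ± 0.793 and 6.08 ± 1.66 TPM. A gene at 0 counts could still hold up to 3 counts in a library, which for 1 kb of exon is 0.286 TPM in replicate 1 and 1.05 TPM in replicate 3.

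The spread between the 4 libraries was then tested gene by gene. Xist, the noncoding RNA that coats the inactive X chromosome, varied beyond the trend of its abundance, at 177 and 193 TPM in replicates 1 and 2 and 2.15 and 0.598 TPM in replicates 3 and 4 (ENSMUSG00000086503.3, chromosome X, positions 103460375 to 103483217, mm10). It was the only one of 12156 genes past the threshold (edgeR quasi-dispersion test, adjusted p = 0.002227), and 596 genes had an unadjusted p under 0.05. The Y-chromosome genes went the other way: Ddx3y had 0.165 and 0.133 TPM in replicates 1 and 2 and 59.7 and 55.2 TPM in replicates 3 and 4, and Eif2s3y had 0.0458 and 0.133 against 72.3 and 68.9 TPM. Kdm5d and Uty had at most 0.0364 and 0.0584 TPM in replicates 1 and 2, and 6.87 to 7.80 and 9.07 to 10.7 TPM in replicates 3 and 4. These 4 genes were removed before the main test by a filter that requires counts in every library. With a filter on the mean count instead, at least 50, 5 genes passed, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, with adjusted p from 0.008678 to 0.03166. Without any filter the test called 126 genes, DESeq2 marked 103 as dispersion outliers, and without replicate 4 the edgeR test called 20.

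**Figure D2:**
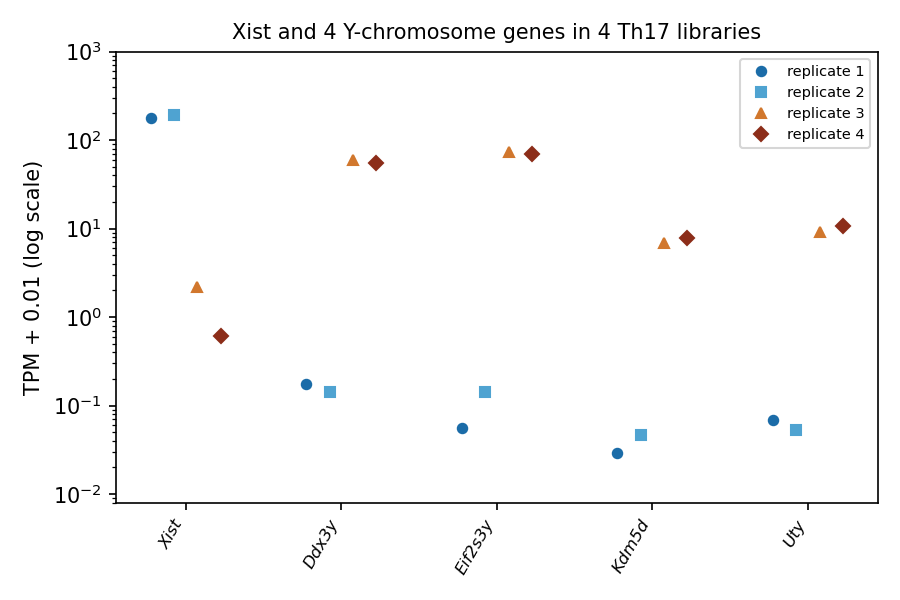
TPM plus 0.01 on a log axis for Xist and 4 Y-chromosome genes; each symbol is 1 library. Xist is at 177 and 193 TPM in replicates 1 and 2 and at 2.15 and 0.598 TPM in replicates 3 and 4, and the 4 Y-chromosome genes take the opposite order.

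Below the threshold of the main test, the next genes by rank shared a pattern of libraries. They are named here after their values were seen. Of the 25 genes ranked after Xist (adjusted p from 0.2891 to 0.4245), 21 were highest in replicate 4 and lowest in replicate 3, and 3 were the reverse, with 2.08-fold to 6.92-fold between the extreme libraries. Ndrg1, a gene induced by low oxygen, had 79.3, 82.7, 38.9 and 165 CPM in replicates 1 to 4. The mitophagy gene Bnip3 had 67.4, 72.0, 42.2 and 131 CPM, the costimulatory receptor gene Tnfrsf9 111, 132, 79.0 and 248 CPM, and the interferon-induced Oas3 14.4, 23.1, 7.04 and 48.7 CPM. Il9 took the reverse order with 65.9, 51.7, 122 and 39.8 CPM. Each of these named genes was called when no filter was used (edgeR quasi-dispersion test, adjusted p from 2.666e-06 to 3.868e-05). Each was also marked as a DESeq2 dispersion outlier. All of them but Bnip3 were called without replicate 4 (same edgeR test, adjusted p from 0.001759 to 0.03488). Their standing therefore depends on the setting.

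Gene lists fixed before the data were examined spread unequally between the libraries. The interferon response list had a median coefficient of variation of 67.2% over its 6 tested members, above all 10000 random lists matched on expression (their median was 15.3%), and Usp18 ranged from 0.754 TPM in replicate 3 to 7.03 TPM in replicate 4. The pathogenic and non-pathogenic Th17 signatures had 21.9% and 21.7%, at the 99.98th and 100th percentile, and the glycolysis list had 11.1%, at the 100th. The oxidative phosphorylation, cholesterol synthesis, T-cell identity and cell-cycle lists had 4.17%, 4.89%, 5.02% and 5.77%, between the 17.75th and the 72.86th percentile. The Th17, Th1, Treg, Tfh and naive T-cell lists had 8.23%, 14.2%, 15.7%, 13.1% and 11.6%, between the 99.46th and 99.91st percentile, and Th2 genes 5.47% at the 29.39th. The remaining lists had 7.76% for activation (98.65th), 6.97% for cytokine receptors (87th), 13.9% for aryl hydrocarbon receptor targets (83.47th), 9.61% for stress genes (70.3rd), 29.7% for natural killer genes (76.38th) and 25.1% for B-cell genes (95.81st). Replicate 4 carried part of this spread. Without it the medians of the pathogenic, Th1, naive and glycolysis lists were 13.3%, 8.21%, 5.35% and 7.04%, and the cholesterol median was 3.23%. The Th1 and naive lists then lay at the 81.81st and 80th percentile of their random lists. The pathogenic and glycolysis lists stayed high against theirs, at the 99.28th and 99.95th. Without replicate 3 the non-pathogenic and glycolysis medians were 14.55% and 8.90%, both still at the 100th percentile.

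In several lists replicates 4 and 3 shifted in opposite directions. Relative to the mean of the other 3 libraries, the median member of the interferon list was 1.05 log2 units higher in replicate 4 and -0.76 in replicate 3, with replicate 1 also low at -0.43. The shift was not uniform: of its 6 tested members, 4 were higher in replicate 4 and 2 were higher in replicate 3. In replicates 4 and 3 the glycolysis list was at 0.24 and -0.24, the pathogenic signature at 0.38 and -0.20, the Treg list at 0.24 and -0.31 and the activation list at 0.13 and -0.16. Of the tested members, 9 of 10 Treg and 11 of 14 activation genes were higher in replicate 4. Higher in replicate 3 were 4 of 10 Treg and 5 of 14 activation genes. The non-pathogenic signature moved the opposite way, at -0.51 in replicate 4 and 0.51 in replicate 3, as did aryl hydrocarbon receptor targets at -0.32 and 0.30 and cell-cycle genes at -0.14 and 0.14. The naive list was at 0.18 in replicate 4 and near 0 in replicate 3. The T-cell identity list was at 0.08 in replicate 4 and -0.11 in replicate 3, and the Th17 list at -0.12 and 0.14. Random lists matched on expression had medians from -0.05 to 0.04 in replicate 4 and from -0.03 to 0.06 in replicate 3. Those for the cell-cycle list were -0.05 and 0.05, so part of its shift is that of other genes at its expression. Of the lists named here, those higher in replicate 4 lay at the 99.9th percentile of their random lists or above, and those lower at the 2.86th or below. In replicate 3 the naive list lay at the 24.02nd, the higher lists at the 98.75th or above and the lower lists at the 1.14th or below. In replicate 4 the pathogenic members Csf2, Il3 and Stat4 had 61.9, 49.3 and 47.6 TPM, against 28.1, 17.3 and 23.1 TPM in replicate 3, while the non-pathogenic members Il9, Ahr and Ikzf3 had 245, 33.1 and 9.70 TPM in replicate 4 and 734, 61.2 and 19.8 TPM in replicate 3. The change was not uniform within the pathogenic signature, where Tbx21 was lowest in replicate 4 (15.3 TPM, against 21.6 to 22.4 TPM in the others) and Ccl4 was lower in replicates 3 and 4 (218 and 200 TPM) than in replicates 1 and 2 (287 TPM in both). Il22 was higher in replicates 3 and 4 (32.2 and 33.2 TPM) than in replicates 1 and 2 (18.3 and 16.3 TPM). Within the non-pathogenic signature, Il10 ran the other way, at 43.7 TPM in replicate 4 and 32.4 TPM in replicate 3, and Maf had 119 and 123 TPM. A shift of 1 library against the rest also enters, with reversed sign, into the shift of the others, so the opposed signs are not independent.

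**Figure D3:**
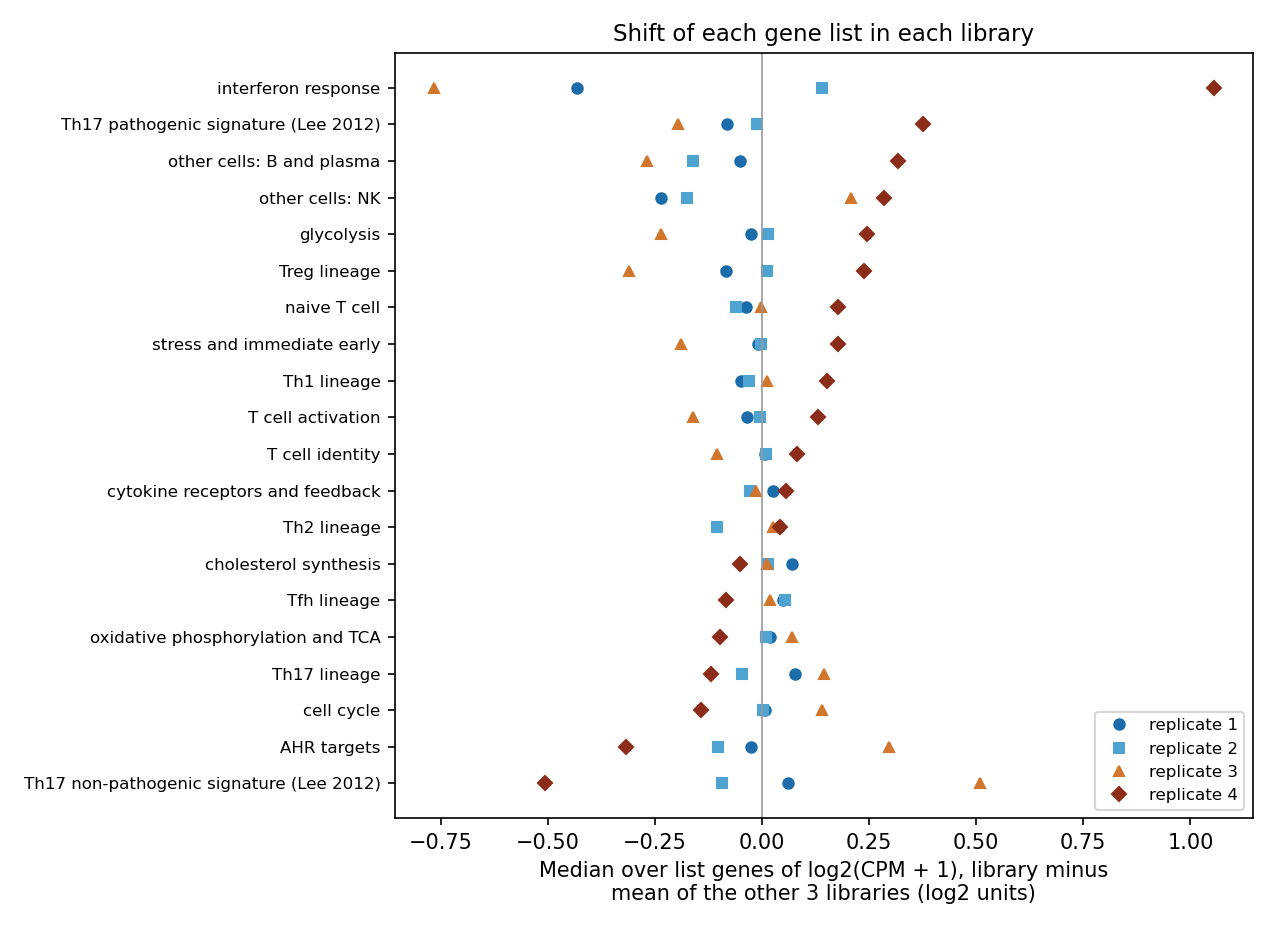
Median over the tested genes of each list of log2(CPM + 1) in 1 library minus the mean of the other 3, in log2 units; each symbol is 1 library. Replicate 4 lies highest for the interferon response list, at 1.05, and lowest for the non-pathogenic Th17 signature, at -0.51.

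All 7 splits of the 4 libraries into 2 sides were fitted to see whether a library or a pair stood apart. Replicate 4 against the others gave 383 of 12156 genes past an adjusted p of 0.05 in edgeR's quasi-likelihood test, 280 of them higher and 103 lower in replicate 4, with the lone library assumed to vary like the others. Among the tested members of the fixed lists, 4 of 16 glycolysis genes were higher (Gpi1, Hif1a, Hk1 and Pfkp), or 11 adjusted over the list alone. So were 4 of 13 pathogenic signature genes (Csf2, Icos, Il3 and Stat4), or 7 adjusted over the list alone, where another 3 were lower. Both Irf7 and Usp18 were higher among 6 interferon genes, or 4 adjusted over the list alone. Of 18 Th17 genes, 3 were lower (Ccl20, Il17a and Il1r1), or 7 adjusted over the list alone, where another 2 were higher. Cd5l was lower among 7 non-pathogenic genes, or 5 adjusted over the list alone. Of 10 Th1 genes, 3 were higher (Il12rb2, Runx3 and Stat4), or 3 adjusted over the list alone, where 1 was lower. Cd2 and Cd3g were higher among 16 T-cell identity genes, or 3 adjusted over the list alone. Adjusted over the list alone, 5 of 9 naive genes were higher (Il7r in the main test), as were 4 of 10 Treg genes (Tnfrsf18) and 4 of 14 activation genes (Icos and Tnfrsf9), with 1 lower in each of the last pair. Socs3 and Atf3 were also higher, and Pdcd1 and Xist lower, Xist by -7.71 log2 units, the largest of the called changes. Xist was also low in replicate 3, at 1.12% of its highest library beside 0.31% in replicate 4. It therefore separates replicates 1 and 2 from 3 and 4, and calls on sex-linked genes do not mark replicate 4 alone. No cell-cycle gene was called, and 3 of 15 were lower adjusted over the list alone. Among markers of other cell types, H2-Ab1 and Ebf1 were higher, by 1.54 and 0.49 log2 units (adjusted p 0.00360 and 0.0414). Each was also the 1 gene of its list called when adjusted over the list alone, which also gave 1 of 4 natural killer genes as higher. The other 6 splits gave 0 genes in edgeR, with 49 to 1193 genes at an unadjusted p under 0.05 and 0 to 15 genes in DESeq2, which gave 261 for replicate 4. For replicates 1 and 2 against 3 and 4, the filter on counts in every library had removed the Y-chromosome genes. Without a filter that split gave 39 genes. Xist passed the filter and was not called in that split. It was at 91.7% and 100% of its highest library in replicates 1 and 2, and at 1.12% and 0.31% in replicates 3 and 4. The 0 calls therefore do not show that these pairs are alike. The count for replicate 4 depended on the libraries it was set against. It was about the same without replicate 1, larger without replicate 2 and largest without replicate 3, each from 1 library against 2. The median size of the change among the genes of the main call was 0.531, 0.55 and 0.464 log2 units without replicates 1, 2 and 3. Without replicate 3, replicate 4 stood only against libraries that also differ from it in Xist and the Y-chromosome genes, so that count is confounded with their difference. The balance of directions also moved, to 603 higher and 454 lower with no filter and 928 higher and 898 lower without replicate 3.

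The share of each class of RNA was then compared between the libraries. Protein-coding genes took 98.9% ± 0.0597 of the counts, long intergenic noncoding RNAs 0.320% ± 0.0635, mitochondrial genes 1.15% ± 0.0990 and the 2 mitochondrial ribosomal RNAs 0.0605% ± 0.00616 (SD, n = 4). The long intergenic class, which holds Xist, took 0.371% and 0.380% in replicates 1 and 2 and 0.258% and 0.273% in replicates 3 and 4. Mitochondrial genes took 1.29% in replicate 4 and 1.08% to 1.13% in the others. The 68 replication-dependent histone genes, whose transcripts lack poly(A) tails, took 0.00304% ± 0.000244 of the counts, and 39 of them were below 1 TPM in the mean. The 7 small structured RNAs without poly(A) tails took 0.00100% ± 8.55e-05, of which Rpph1 had 92.6 ± 6.41 TPM, Rn7sk 5.96 ± 0.976 TPM and Rmrp 1.77 ± 1.25 TPM. Transcripts of 6 mitochondrial protein-coding genes were missing from the counts: mt-Co2, mt-Atp8, mt-Atp6, mt-Nd3 and mt-Nd4l held 0 counts in all 4 libraries and mt-Co3 held 2, whereas mt-Co1, mt-Cytb and mt-Nd1 had 9079 ± 760, 5855 ± 426 and 5373 ± 557 TPM. The 5 genes other than mt-Atp8 share at least 97.99% of their 50-base words with transcripts of other genes, and mt-Co1 and mt-Nd4 share 51.1% and 62.2%, so their values are uncertain in counts limited to reads that map once.

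**Figure D4:**
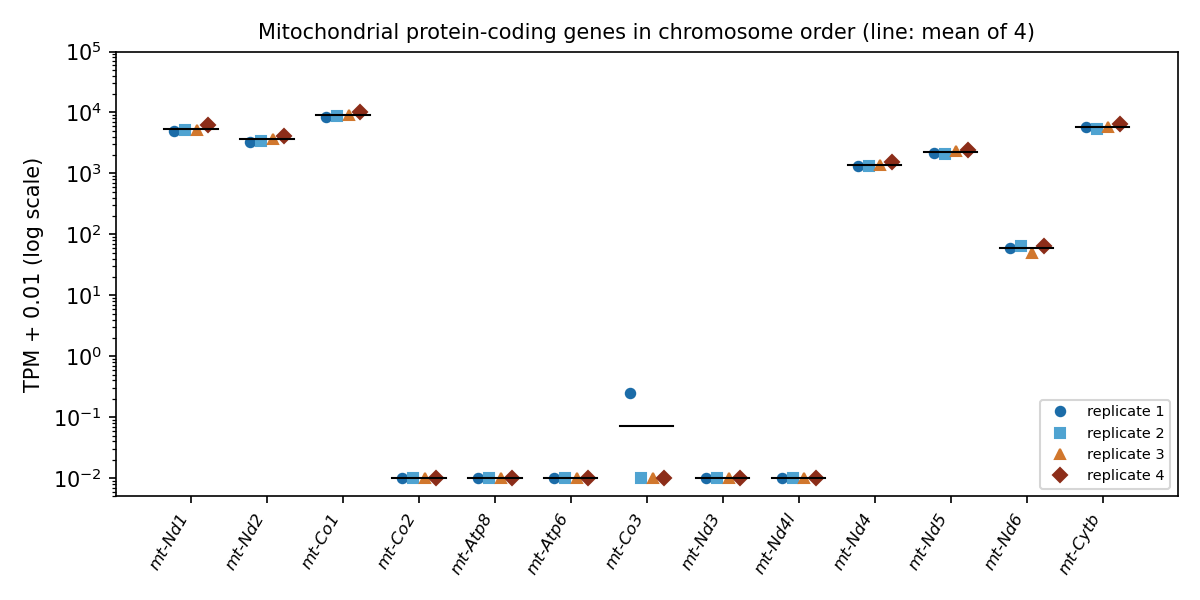
TPM plus 0.01 on a log axis for the 13 mitochondrial protein-coding genes in their order along the chromosome; each symbol is 1 library, and the line is the mean of 4. The 6 genes from mt-Co2 to mt-Nd4l hold 0 to 2 counts, between mt-Co1 at 9079 and mt-Nd4 at 1381 TPM.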

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

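The tests on the mitochondrial genes, the histone genes and the cell-cycle list were chosen after their results, or values close to them, had been seen; thinning and removal of the GC and length trend were chosen after the pattern of replicate 4 but before their own results. Of 218 values examined, 14 had 1 library far from the other 3 by Dixon's criterion (its gap to the nearest, as a share of the whole range), or 6.42%, and chance gives about 5%. Of these, 5 fell in replicate 3 and 5 in replicate 4, and the total lies close to what chance gives.

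Tbx21 was lowest in replicate 4 at 15.3 TPM, against 22.0 TPM in the mean of the others. Foxp3 was highest in replicate 3 at 1.85 TPM, against 0.286 TPM. Sh2d1a, and with it the median of the Tfh list, was lowest in replicate 3 at 32.4 TPM, and Lta and Rn7sk were highest there at 2631 and 7.42 TPM. In replicate 4, mt-Nd1 was highest at 6200 TPM, the pathogenic Th17 signature had a median of 47.6 TPM against 24.7 TPM in the mean of the others, the list of cytokine receptors and feedback had 56.4 TPM, and replication-dependent histone genes took 0.003399% of the counts. The remaining 4 rest on 1 or 2 counts in a single library: Il5 (0.0898 TPM) and Tsix (0.0227 TPM) in replicate 2, and Ptgdr2 (0.0360 TPM) and mt-Co3 (0.243 TPM) in replicate 1.

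Replicate 4 stood apart from the other libraries, with the 383 genes called in edgeR that are described above. The count was about the same without replicate 1 and larger without replicate 2 or replicate 3 (1 library against 2). Without replicate 3, the rest also differ from replicate 4 in Xist and the Y-chromosome genes. These calls rest on the assumption that the lone library varies like the others, since its own spread cannot be measured. The other 6 splits gave 0 in the same test, with 49 to 1193 genes at an unadjusted p under 0.05 and 0 to 15 genes in DESeq2. A difference in depth was tested by thinning every library to the total of the smallest, after which 60.3% of the called genes were called again. The median size of the change among the 364 of them still tested was 0.509 log2 units beside 0.511 before. Thinning leaves the expected size of a change as it was, so these sizes do not bear on depth. The calls made at equal totals argue against unequal totals as their only source. Replicate 4 held 28629187 counts, between replicates 1 and 2 at 34542693 and 23673174, and replicate 3 had the fewest, at 9382661. A trend on GC content or exonic length was tested by removing it from each library: 82.8% of the 383 genes were called again, and the median size of the change among them was 0.512 log2 units beside 0.511 before. The removal moved the share of higher calls, from 280 of 383 to 214 of 379, but the removal also recentres each library, and other settings moved this balance too, so it is not read as an effect of the trend. A difference in the handling, culture or animals of this library stays open. The design gives no group to set against it. A response to low oxygen, for which the test list lay at the 100th percentile in replicate 4, is described among the other observations and stays a hypothesis.

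The absence of counts for 6 mitochondrial genes has a candidate explanation in the counting. Each of mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l shares at least 97.99% of its 50-base words with a transcript of another gene, while the 7 counted genes share at most 62.2%, and the sharing genes are pseudogenes side by side on chromosome 1, from Gm10222 (start 24612407) to Gm28661 (end 24615565). Reads that map to both places were not counted, and the pseudogenes themselves held 5 to 155 counts. The test was first written for all 6 genes, with a share under 10% in any of them as evidence against shared reads, and mt-Atp8 met that bound with 0% shared. It was then treated apart because the search covered annotated transcripts only. The 233 bases between the copies of its neighbours, Gm10925 and Gm28661, are unannotated and were not searched, so for this gene of 204 bases the question stays open. Overlap with a neighbour on the same strand is argued against for mt-Co2 and mt-Nd3, which have 0% of their bases under another gene. The share was 0.128% for mt-Co3, 2.36% for mt-Nd4l and 6.46% for mt-Atp6, but 21.1% for mt-Atp8. Bases were compared rather than read pairs, and reads that overlap several genes were not counted. For mt-Atp8 overlap therefore stays open. No biological explanation was tested.

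RNA without poly(A) tails was scarce in libraries labelled total RNA. Loss of reads shared with other genes could not account for the low values of the 8 histone genes that share under 10% of their words. Their median was 1.501 TPM. The other histone genes share more of their words, so for them this loss stays open. Loss of reads that overlap several genes was not tested for histone genes. Neither kind of loss was tested for the small structured RNAs. Among these, Rn7s1 and Rn7s2 share 100% of their words with each other, so their reads would not be counted. Few dividing cells could not account for the low histone values either, with the cell-cycle list at the 100th percentile of random lists of expressed genes. Histone genes known for transcripts with poly(A) tails (H3f3b, H2afz and 5 others) had a median of 145 TPM, 96.9 times that of the 8 genes, a value consistent with selection of RNA with poly(A) tails, as in the name of the linked protocol.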

How the results depend on the processing

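The alternatives were fixed before the data were examined, except for the splits with thinned libraries, with the GC and length trend removed and with a replicate left out, which were chosen after seeing the data. All 5 list contrasts and 12 gene pairs kept their sign under every alternative run (40 and 72 values), from 1.44 to 6.00 log2 units for the lists; the exact sign-flip test cannot pass 0.05 with 4 libraries, so this says nothing of significance. The count of 11622 detected genes stayed within 1.5 times under all 7 alternatives. Posterior mean TPM were not run. No paired analysis was possible because the series holds 1 group. Depth limits the low genes: 1 count in 1 kb of exon was 0.0953 TPM in replicate 1 and 0.351 TPM in replicate 3.

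The 1 variable gene became 126 with no filter, 5 with a mean of at least 50 counts and 103 by DESeq2 dispersion outliers, all of which hold Xist; leaving out each replicate gave 1 to 20. The estimated prior degrees of freedom rose from 4.78 to 14.4 with no filter. All 103 DESeq2 genes were among the 126.

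Replicate 4 against the others (383 genes) gave 1057 with no filter and 370 to 1826 with another replicate left out. For the other splits, each at 0 in the main test, no filter gave 5 for replicate 1, 1 for replicate 2, 116 for replicate 3, 39 for replicates 1 and 2 against 3 and 4, 374 for 1 and 3 against 2 and 4 and 112 for 1 and 4 against 2 and 3. DESeq2 gave 1 for replicate 2, 15 for replicate 3, 5 for 1 and 2 against 3 and 4 and 11 for 1 and 3 against 2 and 4. Thinning gave 1 for 1 and 2 against 3 and 4, a split in which the main test had not called Xist. The cause was not tested.

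With TPM rescaled over nuclear protein-coding genes, the Th17 and Tfh medians were 216 and 38.7 TPM. Percentiles against expressed genes were 8.7 (Th1), 0 (Th2), 49.92 (Treg), 63.14 (Tfh) and 96.09 (naive). As shares of TPM in place of counts, protein-coding genes took 96.0%, mitochondrial genes 2.95%, mitochondrial ribosomal RNA 0.154%, histone genes 0.0126% and small structured RNAs 0.0102%, since short genes weigh more in TPM. Of 100 alternative values of list variability, 17 moved by more than their bootstrap spread.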

Other observations

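The test of cells of both sexes was chosen after its result had been seen. The list for the hypoxia test was chosen after the most variable genes had been seen, and before its own result.

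Among the 20 most abundant protein-coding genes outside mitochondrial and ribosomal protein genes were, besides Il17f and Il17a, the galectin gene Lgals1 at 7236 ± 182 TPM, the inhibitory receptor gene Ctla4 at 2801 ± 373 TPM and the cytokine gene Lta, which encodes lymphotoxin alpha, at 2114 ± 346 TPM (SD, n = 4). From the non-pathogenic signature, Il9 had 425 ± 216 TPM and Cd5l, a regulator of lipid metabolism, 309 ± 56.2 TPM. Genes of the pathogenic signature ran from Ccl4 and Ccl3 at 248 ± 45.5 and 200 ± 20.6 TPM down to Csf2 at 38.9 ± 15.6 and Gzmb at 1.34 ± 0.717 TPM. The list medians were 48.7 ± 8.75 TPM for the non-pathogenic and 30.4 ± 11.5 TPM for the pathogenic signature. In replicate 4 alone the order was reversed, at 43.7 and 47.6 TPM. These medians are the values of single members in that library, Il10 and Stat4.

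A response of the kind driven by hypoxia-inducible factors may lie behind the order of replicates 4 and 3 in glycolysis genes. To test this on other genes, a list of 19 textbook targets was written that left out the glycolysis list and a few targets noticed among the most variable genes, and 18 were measured. The values of its members had not been looked up, but the list was not cleared of called genes: Mxi1, Gbe1, Ero1l, Fam162a, Higd1a and Stc2 were called in the split of replicate 4, and Mxi1 and Higd1a were among the 126 variable genes with no filter. Of these, 17 were higher in replicate 4 than in the mean of the others, with a median of 0.38 log2 units, at the 100th percentile of matched random lists, and 1 of 18 was higher in replicate 3, with a median of -0.32. Of members not called, Ddit4 had 388 CPM in replicate 4 and 239 CPM in replicate 3. Pfkfb3, Pfkfb4 and Car9 were not highest in replicate 4, and the other members not called were. Pfkfb3 had 73.8 CPM there and 79.3 CPM in replicate 1. Pfkfb4 and Car9 had 14.2 and 1.24 CPM there and 15.7 and 1.39 CPM in replicate 2. The genes of such a list are regulated together, so this describes the libraries and does not measure how often such cultures differ. The labels give no density or oxygen level that could be set against it.

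Xist and the Y-chromosome genes were high in different libraries, though all 4 carry 1 donor label and sex was not recorded. If every library held cells of animals of both sexes, both would be high in each. The lower of the 2 reached at most 1.12% of its highest library, for Xist in replicate 3, which argues against such a mixture. The 4 Y-chromosome genes summed to 0.288 and 0.344 TPM in replicates 1 and 2 and to 148 and 143 TPM in replicates 3 and 4. With Xist reversed, this argues against 1 animal as the source of all 4 libraries. The values may reflect female animals behind replicates 1 and 2 and male animals behind replicates 3 and 4. The donor label may then stand for the strain, and the labels used here do not decide it.

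H2-Ab1, which encodes 1 chain of a class II antigen-presenting molecule, had 61.8 TPM in replicate 4 and 11.8 TPM in replicate 3, while its partner H2-Aa held 0 counts in all libraries and shares 0.514% of its 50-base words with other genes.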
